A study of Mus musculus with 6 samples.

How the data were processed

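The measurements were 6 Affymetrix mouse arrays with 45101 probe sets, hybridised with biotin-labelled RNA from mpkCCD cells, per the labels' protocols. The values deposited by the authors were MAS5 signal intensities on a linear scale, made with Affymetrix Expression Console 1.1, per the submitters' processing notes. The mean of each array without the lowest and highest 2% of probe sets was 500, so the arrays had been scaled to a common level, as found from the deposited signal intensities. The scaling target itself and any further step are not given in the sources used here. MAS5 subtracts mismatch probes, so low signals are noisy, and a common scaling factor per array assumes that the average signal does not differ between lines. No detection calls or scanner files were used here.

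Samples were grouped by the labels, which describe clone 2 as not expressing AQP2 and clones 3, 9, 10 and 11 and the original cells as expressing it. The original cells were taken as the cells the clones were grown from, per the series' design text, while their sample title calls them a clone. Replicate numbers within a group are names and pair no samples. The 64 control probe sets were left out. Gene symbols came from the array platform's annotation, updated through gene identifiers to a gene table of assembly GRCm38.p6. Of 45037 probe sets, 34945 had 1 gene, 932 had several and 9160 had none named, and 34741 of the first had a current symbol. A gene was represented by its probe set with the highest mean signal, and no gene was named from a probe set with several. Probe sets with several or no gene stayed in the tests, 530 and 2812 of them past the filter.

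Signals were used as deposited, as log2(signal + 18.85), the offset being the 25th percentile of all values, so differences of low signals are understated. Probe sets with a mean signal over the 6 arrays above 85.46, the median, were kept, which left 22518 probe sets and 10342 genes. A gene low in most lines could thus be kept only through a high value in a single line. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a mean-variance trend), with Benjamini-Hochberg adjustment over probe sets and an adjusted p under 0.05 as the threshold. All tests were two-sided unless stated. The clone 2 and slope fits had 4 residual degrees of freedom, and the fit of the original cells had 3. In the slope fit the predictor was the log2 value of the only Aqp2 probe set, which was left out of the tested ones. Clone 2 did not stand far enough from the other lines in Aqp2 to bar a pooled correlation (gap over range 0.500, critical value 0.625). Correlations were tested by all 720 pairings of the 6 arrays, whose smallest two-sided p is 0.00139 for r and 0.00278 for rho, and p-values were adjusted over 12 relations. Values without an SD in the text come from a single array.

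Before the data were examined, 19 gene lists were fixed. These were principal cell, intercalated cell, proximal tubule, loop of Henle and distal convoluted tubule, fibroblast and mesenchymal, epithelial junction and keratin, endothelial and leukocyte, vasopressin and cAMP signalling, ETS, HOX and other kidney transcription factors, AQP2 vesicle trafficking, osmotic response, aldosterone and glucocorticoid response, cell cycle, interferon response, hypoxia and glycolysis, cholesterol synthesis, and Y-linked genes. Of these, 18 were tested with camera at its preset correlation of 0.01 and again with an estimated correlation, over 1 probe set per gene, and fry was run beside it. Aqp2 was left out of the principal cell test.

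The rule for named genes was also fixed then. It took Aqp2, the 8 largest differences per direction in the clone 2 comparison among called genes whose clone 2 value lay outside the range of the other lines, up to 4 called members per list or, where none was called, the 2 of highest mean signal, and the 5 largest per direction for the slope and the original cells, filled up to 4 by the smallest unadjusted p. Genes named outside this rule are said to be so.

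On simulated data made from the same signals, with 200 changed probe sets in each of 5 runs, the clone 2 test over 22518 probe sets recovered 1.2% of log2 changes of 0.5, 26% of 1, 76.8% of 2 and 96% of 4, and 3.1% of its calls were false. For the original cells the shares were 0%, 16%, 69.2% and 93.6%, with 3.5% false calls. For the slope over 22517 probe sets, with sizes given over the range of Aqp2, they were 0.8%, 17.6%, 67.6% and 92%, with 3.9% false calls. Of 200 unshifted lists of 20 genes, camera called 3%. The simulated noise was independent between probe sets, so genes that move together were not represented. These shares therefore do not give the error rates of the real arrays, where genes of a chromosome shifted together.

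Alternatives fixed before the data were examined were an offset of 0 or doubled, no filter or a filter at the 75th percentile, quantile normalization, median centring, eBayes without trend or robust, 1 probe set per gene, leaving out probe sets that can match several transcripts, a 2-fold minimum, each line left out in turn, Aqp2 on the linear scale, rank correlation, and a comparison of the original cells with all 5 clones. Leaving out an array keeps at least 1 array per group, except in the slope fit without clone 2, which keeps only expressing lines. A lone array was again assumed to vary like the others. Removal of each line's median over the genes of each chromosome, and camera with an estimated correlation while each line was left out, were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.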

Results

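Gene expression was measured on 6 Affymetrix arrays in mpkCCD cells, a mouse cell line from the cortical collecting duct of the kidney. Principal cells of this duct carry the water channel aquaporin 2 (AQP2, gene Aqp2), whose expression depends on the hormone vasopressin. The cells were the original cells and clones 2, 3, 9, 10 and 11, taken here to be grown from them, all kept with the vasopressin analog dDAVP at 0.1 nM for 5 days. The labels put clone 2 alone in the group without AQP2 expression and the 5 other lines in the AQP2-expressing group. Each line had 1 array, so p-values rest on the spread between arrays, in which line, culture and array differences cannot be told apart. Clone 2 and the original cells were assumed to vary like the lines they were compared with. With a single line labelled as not expressing AQP2, that label cannot be separated from other traits of clone 2. The number of arrays limits the precision. Median signals lay between 79.6 in clone 2 and 88.6 in clone 10, and every line but clone 2 had at least 84.3. The 25th percentile (17.5) and the highest signal (35549) were also lowest in clone 2. The ratio of the 3′ to the 5′ probe set lay between 1.58 and 1.76 for beta-actin and between 0.824 and 0.887 for Gapdh. Across 22518 probe sets, the correlation between expressing lines was 0.953 to 0.981, and that of clone 2 with them was 0.930 to 0.953.

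Aqp2 was lowest in clone 2 and varied widely among the expressing lines. Its signal was 159.3 in clone 2, 1066.4 in clone 10, 1697.9 in clone 3, 3822.4 in the original cells, 4683.4 in clone 9 and 6577.7 in clone 11. The expressing lines averaged 3570 ± 2243 (SD, n = 5), which was 22.4 times the signal of clone 2, and the highest of them exceeded the lowest by 6.17 times. The log2 difference of clone 2 was -4.05 (SE 0.795, limma adjusted p = 0.0388). The adjusted p rose to 0.0535 without clone 11 and to 0.0869 without the original cells, and it was 0.0814 with no filter on low signal, 0.0857 without the mean-variance trend and 0.157 with a robust fit. Over all settings tried it lay between 0.0173 and 0.157. The signal of clone 2 lay at the 58.7th percentile of its array, and no detection call was used here, so absence of the transcript was not shown.

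**Figure D1:**
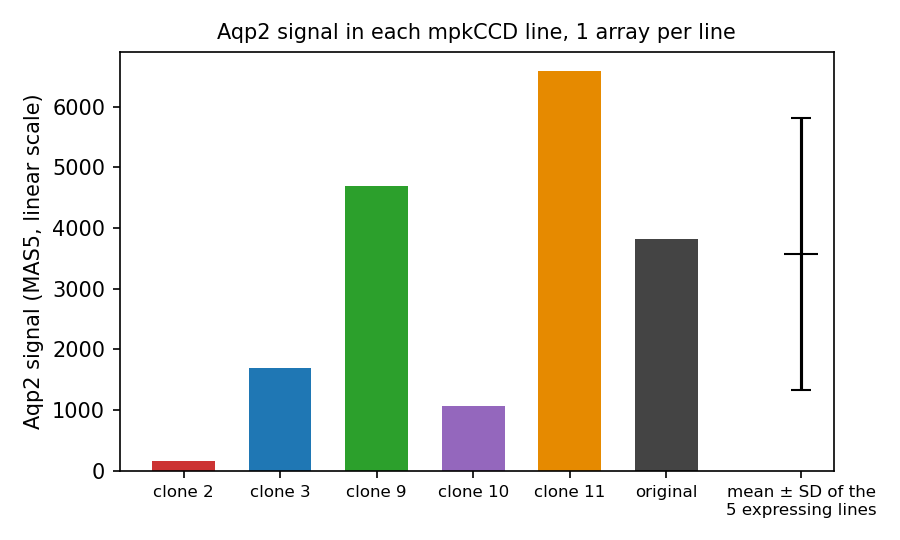
Bars show the Aqp2 signal (MAS5, linear scale from 0) in each of the 6 lines, and the black mark with its bar shows the mean ± SD of the 5 AQP2-expressing lines. Clone 2 stands at 159.3, and the expressing lines range from 1066.4 to 6577.7.

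The comparison of clone 2 with the AQP2-expressing lines asks which other transcripts separate the line labelled as not expressing AQP2 from those labelled as expressing it. The genes past the test that were most raised in clone 2 were Ak4, Ifi27 and Rsad2, and several of the others named here are known as induced by interferon, a grouping from general knowledge, since of these only Rsad2 was on the fixed interferon list. Ifi27 had a signal of 3947.7 in clone 2 against 115 ± 66.2 (SD, n = 5), a log2 difference of 5.00 (SE 0.470, limma adjusted p = 0.00381). Rsad2, which encodes the antiviral protein viperin, reached 5827 against 240 ± 225 (log2 difference 4.94, SE 0.953, limma adjusted p = 0.0374), although this call was lost without clone 10 (adjusted p = 0.058) or the original cells (0.0739), with no filter (0.0783), without the mean-variance trend (0.0818) and with a robust fit (0.141). Further interferon-induced genes were Ifi27l2a (log2 difference 4.57), Oas3 (4.05), an oligoadenylate synthetase, and Cmpk2 (3.94), a mitochondrial nucleotide kinase. Outside this group, the largest rises were in Ak4, a mitochondrial adenylate kinase (5.09), S100g, a calcium-binding protein (4.24), and Slc16a3, a lactate transporter (4.20). For Ak4, Ifi27l2a, S100g, Slc16a3 and Oas3 the mean of the expressing lines was at most 30.5 signal units, so the size of their difference depended on the offset added before the logarithm. The call for S100g was lost without the original cells (adjusted p = 0.0513) and with an offset of 0 (0.142), as was that for Ak4 with an offset of 0 (0.0832).

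Besides Aqp2, the genes past the test that were most lowered in clone 2 were Rbms3, Epb41l3, Eya4 and Maoa. Rbms3, an RNA-binding protein, had a signal of 26.3 in clone 2 against 1871 ± 1144 (SD, n = 5), a log2 difference of -5.15 (SE 0.700, limma adjusted p = 0.0108). Epb41l3, a membrane cytoskeleton protein, stood at 37.7 against 1696 ± 986 (log2 difference -4.70), and Eya4, a transcriptional coactivator, at 10.1 against 428 ± 199 (-3.83). Maoa, which encodes monoamine oxidase A, had the smallest adjusted p of the comparison, with 44.0 against 740 ± 104 (log2 difference -3.58, SE 0.226, limma adjusted p = 0.00148). Dram1, a lysosomal membrane protein linked to autophagy, fell by 3.25 on the log2 scale. The protocadherin Pcdh19 fell by 3.04, Col4a4, a chain of the basement membrane collagen, fell by 3.01, and Bcat1, an aminotransferase of branched-chain amino acids, fell by 2.99. With a robust fit the calls for Rbms3 (adjusted p = 0.0694) and Epb41l3 (0.0832) were lost. Other probe sets of the same gene past the filter had the same sign for all 10 of these 16 genes that had any. Not all of them were called: the 1 other probe set of Maoa was not, and of 2 for Pcdh19 only 1 was.

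**Figure D2:**
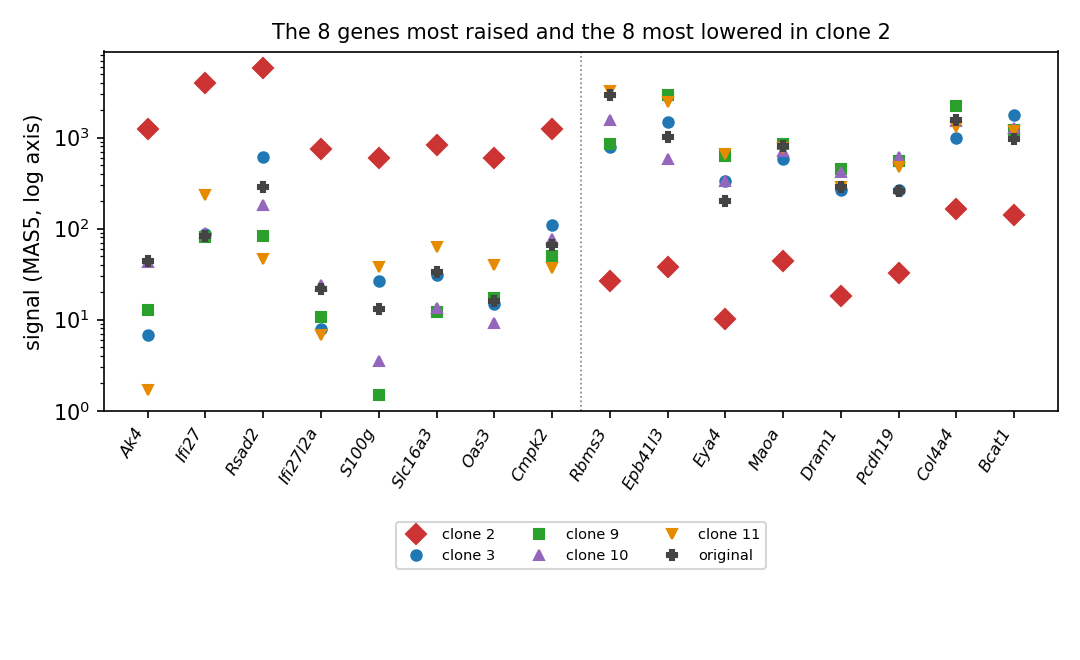
Points show the signal (MAS5, log axis) of each line for the 8 genes named as most raised in clone 2 (left of the dotted line) and the 8 named as most lowered (right). Each point is 1 array, and for every one of the 16 genes the clone 2 point lies outside the range of the 5 expressing lines.

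In all, 560 of 22518 probe sets differed, 184 higher and 376 lower in clone 2, and they named 149 and 252 genes. At an unadjusted p under 0.05 there were 4506 probe sets, where chance gives 1126. With each other line in turn set against the rest, clone 9 gave 32 calls, the original cells 2, clones 3 and 11 gave 1 each and clone 10 gave 0 (limma, with 479 probe sets at an unadjusted p under 0.05 for clone 10). Clone 2 was among the lines these were set against, so its own differences entered their residual spread. Low numbers were partly built in by this, and they are not like for like with the counts of clone 2. The counts moved with the lines included: 118 higher and 202 lower without clone 3, 325 and 618 without clone 9, 115 and 229 without clone 10, 82 and 167 without clone 11, and 45 and 109 without the original cells. All 560 kept their sign in each of these fits, 152 were still called without the original cells, and the count was 76 higher and 134 lower with no filter and 69 and 150 without the mean-variance trend.

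The interferon response list, fixed before the data were examined, was higher in clone 2 as a group. Of its 26 members past the filter, 9 rose, 17 did not pass the test, and all 26 had a positive difference. Members low in the expressing lines could pass the filter only through clone 2, as Gbp2 did, so their positive difference was partly set by the filter. Adjusted over the list alone, 22 rose. The median log2 difference was 2.13, and the list differed from other genes by camera (adjusted p = 2.72e-14), but with an estimated correlation between its genes the adjusted p was 0.164. Oasl2, of the oligoadenylate synthetase family, had a signal of 1783 in clone 2 against 160 ± 107 (log2 difference 3.50), Oasl1 had 1019.9 against 106 ± 60.6 (3.19), and Gbp2, a guanylate-binding protein, had 711.8 against 64.8 ± 30.1 (3.20), each with n = 5 expressing lines. The calls for Oasl1 and Oasl2 were lost without the original cells (adjusted p = 0.0535 and 0.0619), with no filter (0.0565 and 0.0527) and without the mean-variance trend (0.0527 and 0.0576).

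The hypoxia and glycolysis list was also higher, with 2 of 21 members past the test, 9 adjusted over the list alone, and a median log2 difference of 0.46 (camera adjusted p = 0.000163, and adjusted p = 0.177 with an estimated correlation). The members past the test were Ndrg1, a stress-induced gene (log2 difference 0.79), and Slc2a1, a glucose transporter (0.77). Of 29 cell cycle genes, 2 rose, the cyclin Ccne2 (0.97) and Rrm2 (0.76), a subunit of ribonucleotide reductase, and 2 adjusted over the list alone (camera adjusted p = 0.0133, and adjusted p = 0.67 with an estimated correlation). In the list of the loop of Henle and distal convoluted tubule, S100g and Bst1, a cell surface enzyme of NAD metabolism (1.99), rose among 5 members, both also adjusted over the list alone (camera adjusted p = 0.0101, and adjusted p = 0.201 with an estimated correlation). Without the original cells the calls for Ndrg1 (adjusted p = 0.0863), Slc2a1 (0.0829), Ccne2 (0.0711), Rrm2 (0.0615), Bst1 (0.0808) and S100g (0.0513) were lost. Those for Ndrg1 (0.0674), Ccne2 (0.0551), Rrm2 (0.0611) and Bst1 (0.0694) were also lost without clone 3, those for Ndrg1 (0.0583), Slc2a1 (0.0651) and Ccne2 (0.0655) without clone 10, and those for Slc2a1 (0.053), Ccne2 (0.0702) and Rrm2 (0.0551) without clone 11. The calls for Ndrg1, Slc2a1, Ccne2, Rrm2 and Bst1 were lost with no filter (adjusted p = 0.0971, 0.0803, 0.0664, 0.0783 and 0.0971) and without the mean-variance trend (0.111, 0.104, 0.0737, 0.101 and 0.0974), Bst1 also with quantile normalization (0.0514) and a robust fit (0.0704), and S100g also with an offset of 0 (0.142). With no filter, the list of the loop of Henle and distal convoluted tubule no longer passed (adjusted p = 0.0853).

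Principal cell genes were lower in clone 2 than on average in the expressing lines. The mean log2 signal of the list was 9.62 in clone 2, but it was also low in clone 9, at 9.82, where Aqp2 was second highest, against 10.45 to 10.62 in the other lines. Of 14 members besides Aqp2, 3 fell, 11 did not pass the test, and 7 fell adjusted over the list alone (median log2 difference -0.54, camera adjusted p = 0.00515, and adjusted p = 0.153 with an estimated correlation). Fxyd4, a regulator of the sodium pump, had a signal of 780.9 in clone 2 against 3481 ± 745 (SD, n = 5; log2 difference -2.10, SE 0.278, limma adjusted p = 0.00977). The matrix protein Npnt stood at 3832.7 against 10740 ± 764 (-1.48) and the transcription factor Gata3 at 2109 against 3807 ± 148 (-0.85). With no filter on low signal the list no longer passed (adjusted p = 0.0546), and the call for Gata3 was lost without the mean-variance trend (adjusted p = 0.0576). Avpr2, the vasopressin receptor of these cells, named after its value was seen, did not pass the test, with 1741.9 against 1610 ± 128 (adjusted p = 0.723).

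The aldosterone and glucocorticoid list shared 5 members past the filter with the principal cell list, and that of other kidney transcription factors shared 3. The aldosterone and glucocorticoid list moved the same way as the principal cell list, with 1 of 17 members past the test, Fxyd4, also adjusted over the list alone (camera adjusted p = 0.00515, and adjusted p = 0.153 with an estimated correlation). In the list of other kidney transcription factors, 3 of 34 fell, Nfat5, the factor of the osmotic response (-0.88), Gata3 and Rxra, a retinoid receptor (-0.72), and 5 adjusted over the list alone (camera adjusted p = 0.00515, and adjusted p = 0.153 with an estimated correlation). The calls for Nfat5 and Rxra were lost without clone 3 (adjusted p = 0.0522 and 0.0829), clone 10 (0.0541 and 0.0736), clone 11 (0.0593 and 0.0885) or the original cells (0.055 and 0.1), with no filter (0.0583 and 0.0697) and without the mean-variance trend (0.0826 and 0.0761). That for Rxra was also lost with quantile normalization (0.0602) and median centring (0.0623), that for Gata3 without the trend (0.0576), and the transcription factor list no longer passed with no filter (adjusted p = 0.0546).

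The remaining lists did not differ from other genes by camera. Among 8 intercalated cell genes 1 fell, Aqp6, an intracellular water channel (log2 difference -2.36, limma adjusted p = 0.00648), and here the median difference of 0.15 was opposite in sign to the camera test (adjusted p = 0.893). Of 3 proximal tubule genes 1 fell, Lrp2, which encodes the endocytic receptor megalin, with 116 against 942 ± 121 (SD, n = 5; log2 difference -2.83), and the camera adjusted p was 0.229. Of 5 fibroblast and mesenchymal genes 1 fell, the matrix protein Fn1 (-1.35), and 2 adjusted over the list alone (camera adjusted p = 0.154). Of 16 HOX genes 1 fell, Hoxd8 (-0.79), and 3 adjusted over the list alone (camera adjusted p = 0.141). Of 11 osmotic response genes 1 fell, Nfat5 (camera adjusted p = 0.893), and of 17 cholesterol synthesis genes 1 rose, the sterol dehydrogenase Nsdhl (0.80; camera adjusted p = 0.141). The calls for Hoxd8, Nfat5 and Nsdhl were lost without clone 3 (adjusted p = 0.0698, 0.0522 and 0.0694), clone 10 (0.0691, 0.0541 and 0.0655), clone 11 (0.0856, 0.0593 and 0.0764) or the original cells (0.106, 0.055 and 0.0863), with no filter (0.0971, 0.0583 and 0.0776) and without the mean-variance trend (0.113, 0.0826 and 0.0951), Hoxd8 also with median centring (0.0667) and Nsdhl with quantile normalization (0.0565). For intercalated cell, proximal tubule, osmotic response and cholesterol synthesis genes the number adjusted over the list alone was also 1.

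No member passed the test in 5 further lists. These were 27 epithelial genes, with the keratins Krt18 at 25158 in clone 2 against 29320 ± 2490 and Krt8 at 19227 against 21940 ± 1780. They also included 27 genes of vasopressin and cAMP signalling, with Gnas, the stimulatory G protein, at 14806 against 15210 ± 1259 and Gnai3, an inhibitory one, at 5173 against 6544 ± 192. Among 37 genes of AQP2 vesicle trafficking, the chaperone Hspa8 stood at 24791 against 30450 ± 3286 and the membrane protein Mal at 19882 against 21890 ± 2444. Among 17 ETS factors, Ehf stood at 3156 against 3283 ± 608 and Ets2 at 2986 against 3105 ± 402, and 2 members fell adjusted over the list alone. Of 4 endothelial and leukocyte genes, Cd14 had 1891 against 2161 ± 435 and Csf1r 1838 against 2049 ± 472, each with n = 5. The camera adjusted p was 0.41 for epithelial, 0.764 for signalling, 0.41 for trafficking, 0.893 for ETS and 0.893 for endothelial and leukocyte genes. None of the 7 measured Y-linked genes passed the filter, so that list was not tested. By fry, which tests whether the genes of a list move on balance one way and does not compare them with other genes, 8 of 18 lists passed in clone 2. These were the lists of interferon response (adjusted p = 0.0141), hypoxia and glycolysis (0.0141) and loop of Henle genes (0.0188), all up, and of other kidney transcription factors (0.00301), aldosterone response (0.0114), principal cell (0.029), fibroblast (0.0139) and proximal tubule genes (0.029), all down. Fibroblast and proximal tubule genes thus passed by fry and not by camera, and cell cycle genes by camera and not by fry (adjusted p = 0.299).

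**Figure D3:**
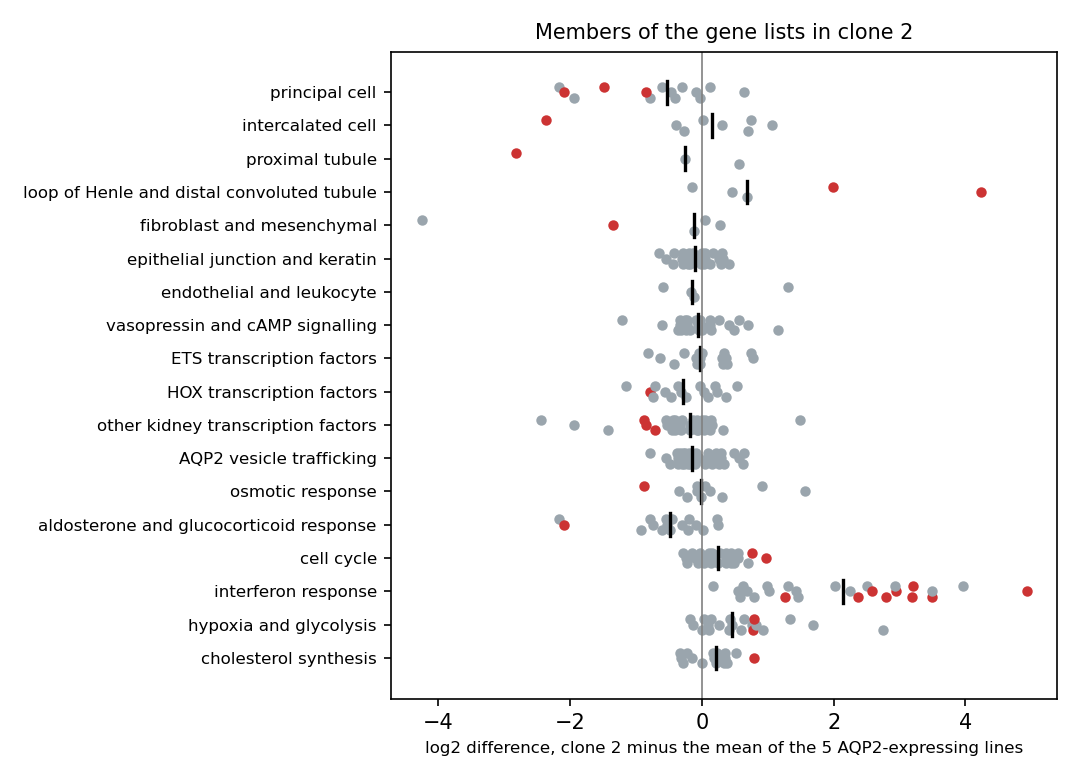
Each point is 1 gene, at its log2 difference between clone 2 and the mean of the 5 AQP2-expressing lines (horizontal axis), grouped by list (vertical axis, members past the filter, without Aqp2). Red points passed the test at an adjusted p under 0.05, grey points did not, and the black line is the list's median, 2.13 for the interferon response and -0.54 for principal cell genes.

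Clone 2 also differed by chromosome, with gene positions from assembly GRCm38.p6. The median of 297 X-linked genes lay 0.47 above that of the other lines on the log2 scale, and the median of 507 genes of chromosome 17 lay at -0.38. S100g, Nsdhl, Maoa and Pcdh19 are X-linked, the last 2 being lower in clone 2, Epb41l3 lies on chromosome 17, and Col4a4 and Fn1 lie on chromosome 1. Named genes on other shifted chromosomes included Ifi27, Rsad2, Ifi27l2a and Cmpk2 on chromosome 12 (median 0.197). Eya4 and Dram1 lie on chromosome 10 (median -0.251). The differences of these genes were larger than the medians of their chromosomes. After each line's median was removed from the genes of each chromosome, a setting chosen after seeing the data, 112 probe sets were higher and 308 lower, and the calls for Bst1, Hoxd8, Rxra, Ccne2, Rrm2, Ndrg1, Slc2a1 and Nsdhl were lost. A lost call need not mean a lost difference. In the same order, the log2 difference nearest to none in any setting was 1.79, -0.68, -0.61, 0.82, 0.57, 0.67, 0.62 and 0.36. The 7 lists that passed by camera still did so at the preset correlation, and the HOX list passed as well (adjusted p = 0.0272).

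The slope on AQP2 addresses the study's stated aim, transcripts whose level follows Aqp2 mRNA across the lines. The genes with the steepest rise were Rbms3, Epb41l3, the cadherin Cdh2, the gap junction gene Gja1 and Eya4. Per doubling of Aqp2, Gja1 rose by 0.91 on the log2 scale (SE 0.0951, limma adjusted p = 0.0196), from 9.6 in clone 2 to 830.3 in clone 11, and Epb41l3 rose by 1.04 (SE 0.115, limma adjusted p = 0.0196). The slopes of Rbms3, Cdh2 and Eya4 were 1.04, 1.04 and 0.79. The steepest falls were in Rsad2 (-1.11), Ak4 (-1.02), Rtp4, an interferon-induced chaperone (-1.02, SE 0.138, limma adjusted p = 0.02), the X-linked Dock11 (-0.91), and Ifi27l2a (-0.88).

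The 10 genes were chosen for their slope on Aqp2 in the same 6 arrays, so a high correlation and a small p were set by that choice and are no further evidence. Across the 6 lines, the correlation of Gja1 with Aqp2 was r = 0.964 (exact permutation p = 0.0056, adjusted 0.0367 over 12 relations) and Spearman's rho = 0.943 (p = 0.0167, adjusted 0.0777), and without clone 2 and clone 11, the lines farthest from the median of Aqp2, r was 0.837. For Rtp4, r was -0.930 (exact permutation p = 0.0097, adjusted 0.0367), rho was -0.886 (p = 0.0333, adjusted 0.0777), and r was -0.764 without those lines. For Rbms3, Eya4, Rsad2, Ak4 and Ifi27l2a r was 0.882, 0.896, -0.912, -0.895 and -0.893 over all lines but 0.0952, 0.218, -0.406, -0.146 and -0.240 without clone 2 and clone 11, so these relations rested on those lines. For Epb41l3, Cdh2 and Dock11 r was 0.952, 0.916 and -0.868, and 0.736, 0.805 and -0.798 without them. No Spearman's rho of the 12 relations passed after adjustment (lowest adjusted exact permutation p = 0.0777).

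In all, 230 probe sets rose and 167 fell with Aqp2 among 22517. Of these 397, 139 were also called in clone 2, all in the direction that low Aqp2 in clone 2 gives, and both tests use the same 6 arrays. The count was 3 rising and 0 falling without clone 2, and 0 and 0 without clone 11, and all 10 named slopes lost their call in both fits (adjusted p between 0.193 and 0.879 without clone 2, and between 0.0661 and 0.118 without clone 11). Calls were also lost without clone 9 for Ak4 (adjusted p = 0.0503), Dock11 (0.0527), Eya4 (0.0531) and Ifi27l2a (0.0573), without the original cells for Ak4 (0.0576), Dock11 (0.0546), Ifi27l2a (0.0847) and Rbms3 (0.0768), and without clone 3 for Rbms3 (0.0538). The count of rising and falling probe sets was 102 and 89 without clone 3, 134 and 124 without clone 9, 392 and 256 without clone 10, and 41 and 49 without the original cells. All 10 named slopes also lost their call without the mean-variance trend (adjusted p between 0.0593 and 0.101), 7 with no filter (between 0.062 and 0.0972), all but those of Epb41l3, Gja1 and Rtp4, and 6 with a robust fit (between 0.0512 and 0.141), all but those of Epb41l3, Gja1, Ak4 and Ifi27l2a. The call was lost with an offset of 0 for Ak4 (0.0699), Dock11 (0.0533) and Ifi27l2a (0.0794), and for Ifi27l2a also with quantile normalization (0.0514) and 1 probe set per gene (0.0547). With chromosome medians removed, a setting chosen after seeing the data, Rbms3 (0.0627), Ak4 (0.0548), Dock11 (0.0861) and Ifi27l2a (0.0641) lost it. The count was 0 and 1 without the mean-variance trend (4474 probe sets had an unadjusted p under 0.05 in the fit with it, where chance gives 1126), 30 and 21 with no filter, and 3 and 4 with Aqp2 on the linear scale.

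Interferon response genes fell with Aqp2 as a group. Of 26 members, 14 fell and 12 did not pass the test, 21 fell adjusted over the list alone, and the median slope was -0.41 (camera adjusted p = 2.5e-15, and adjusted p = 0.41 with an estimated correlation). The mean log2 signal of the list was 10.51 in clone 2, 9.00 in clone 3, 8.61 in the original cells, 8.52 in clone 10, 8.10 in clone 9 and 8.02 in clone 11, and its correlation with Aqp2 was r = -0.933 (exact permutation p = 0.0194, adjusted 0.0371; rho = -0.829, p = 0.0583, adjusted 0.0777) but -0.527 without clone 2 and clone 11. The hypoxia and glycolysis list (0 of 21 past the test, 4 falling adjusted over the list alone, camera adjusted p = 0.00825) and that of the loop of Henle and distal convoluted tubule (1 of 5 falling, Bst1, 2 adjusted over the list alone, camera adjusted p = 0.0166) also leaned down. With an estimated correlation their adjusted p was 0.504 and 0.41. The loop of Henle list also no longer passed by camera with no filter (adjusted p = 0.293). The same held with the mean of each gene's probe sets in place of a single one (adjusted p = 0.0531).

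The principal cell list (1 of 14 rising, 6 adjusted over the list alone, camera adjusted p = 0.0312), the aldosterone and glucocorticoid list (0 of 17, 4 adjusted over the list alone, camera adjusted p = 0.0134) and the other kidney transcription factors (1 of 34 rising, and 6 rising and 2 falling adjusted over the list alone, camera adjusted p = 0.0249) leaned up with Aqp2. With an estimated correlation each of these had an adjusted p of 0.41. With no filter, the principal cell list (adjusted p = 0.339) and the other kidney transcription factors (0.136) no longer passed by camera. The transcription factor list was also lost with a filter at the 75th percentile (adjusted p = 0.255). The member that rose in both the principal cell and the transcription factor list was Gata2, a zinc finger transcription factor named after its value was seen (slope 0.47, limma adjusted p = 0.0335). Without clone 2, the principal cell, other kidney transcription factor and hypoxia and glycolysis lists turned to the opposite direction, short of the threshold (adjusted p = 0.783, 0.982 and 0.753), the aldosterone and loop of Henle lists were lost (0.825 and 0.529), the interferon list still passed (0.00193), and the cell cycle list passed (3.25e-05). Without clone 9 the HOX list passed (adjusted p = 0.0439). None of these held with an estimated correlation (adjusted p = 0.562 for interferon and 0.562 for cell cycle genes without clone 2, and 0.495 for HOX genes without clone 9), a setting chosen after seeing the data, and by exact permutation the slope of the interferon list's mean within the 5 expressing lines had a one-sided p of 0.117. The mean of the principal cell list did not follow Aqp2 (r = 0.481, exact permutation p = 0.3597, adjusted 0.36; rho = 0.2, p = 0.7139, adjusted 0.714), and r turned to -0.770 without clone 2 and clone 11. The other 12 lists did not pass by camera. Members past the test there were Cdh2 and Fn1 (slope 0.28), 2 of 5 fibroblast and mesenchymal genes, and Pkia, an inhibitor of protein kinase A (slope 0.28), 1 of 27 genes of vasopressin and cAMP signalling, Fn1 and Pkia being named after their values were seen. By fry, 0 of 18 lists passed for the slope (lowest adjusted p = 0.0518, with 6 lists at an unadjusted p under 0.05).

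The original cells were compared with the 4 expressing clones to ask what set them apart. They are taken as the cells that were cloned, as the study design has it, although the title of their sample calls them a clone as well. A single transcript passed the test, the X-linked Xist, the noncoding RNA that silences an X chromosome. Its signal was 6936.5 in the original cells against 69.2 ± 16.4 in the expressing clones (SD, n = 4), a log2 difference of 6.32 (SE 0.320, limma adjusted p = 0.00189), and it was 55.2 in clone 2. The call was lost with a filter at the 75th percentile of mean signal (adjusted p = 0.23), and the probe set drops out where those that can match several transcripts are left out. At an unadjusted p under 0.05 there were 449 probe sets, where chance gives 1126. Aqp2 itself had a log2 difference of 0.48 (SE 0.869, limma adjusted p = 1).

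Other genes with the smallest unadjusted p did not pass the threshold. The mucin Muc20 had a signal of 1350 in the original cells against 553 ± 26.9 in the expressing clones (SD, n = 4), Syce2, of the synaptonemal complex, 2843 against 1628 ± 198, and Fam174b 429 against 116 ± 45.9. On the other side, Mettl7a2 had 20.7 against 180 ± 49.3, the F-box genes Fbxo10 and Fbxo42 had 61.1 against 209 ± 36.9 and 456.2 against 948 ± 120, and the homeobox gene Hlx had 16.3 against 116 ± 28.9. Their limma adjusted p was 0.526 for Muc20 and 1 for the rest. None of the 18 lists passed by camera (lowest adjusted p = 0.462, with 0 at an unadjusted p under 0.05), and none by fry (lowest adjusted p = 0.988, also with 0). The interferon response list passed without clone 3 (adjusted p = 4.08e-05), and the proximal tubule list, of 3 genes, without clone 11 (adjusted p = 0.0417), but with an estimated correlation, a setting chosen after seeing the data, the adjusted p was 0.931 and 0.935.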

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

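The tests of a few strongly changed X-linked genes, of chromosome-wide shifts behind the slope on Aqp2, and all those for Xist were chosen after the result was seen, and the patterns themselves were picked out from the data. Among the 5 expressing lines, 61 measures were examined for a line far from the others, and 4 had one, where chance sets apart about 1 in 20 groups, or about 3. That rate does not apply to Xist, Muc20 and Fbxo10, which were among the measures because they had been picked for a difference of the original cells. Ifi27 was 233 in clone 11, where the nearest other line had 89.5. Xist was 6936 in the original cells, where the nearest had 88.9. Muc20 was 1350 in the original cells, where the nearest had 590.3. Fbxo10 was lowest in the original cells, at 61.1, where the nearest had 175.5.

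Xist was high in the original cells and low in all 5 clones, which had 52.4 to 88.9 at the called probe set. A single faulty probe set is argued against by another Xist probe set, which was 84.1 times as high in the original cells as in the highest clone, while the third, of low signal, was 4.43 times as high. Neither of these other probe sets was itself called, and the clones had at most 33.3 at the first of them, so its ratio is not exact. An array of cells unlike the expressing clones is argued against by the correlation of the original cells with those clones. It was at least 0.966, above the lowest value of 0.953 among the clones, that of clones 9 and 10. Closely related cells of another line, or a mixture, could also reach such values, so the correlation cannot exclude them. Another X-linked dosage in the original cells stays open: their X-linked median differed from that of the expressing clones by 0.009 (bootstrap SE 0.011), and an additional but silenced X chromosome would also leave it near 0. No biological explanation was tested, and loss of an Xist-expressing chromosome on cloning, or Xist in a subpopulation of the original cells, may account for it only as a hypothesis.

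In clone 2, genes of whole chromosomes were shifted together, most on the X chromosome (median log2 deviation 0.472, bootstrap SE 0.027), chromosome 17 (-0.383), chromosome 1 (-0.298), chromosome 10 (-0.251) and chromosome 19 (-0.245). A few strongly changed genes are argued against, since 87.2% of the X-linked genes lay above the median of the other lines, and a bias with signal level is argued against, since 0% of 10000 random gene lists matched on mean signal lay as far from 0. The shift ran along the whole X chromosome, the lowest median among 4 blocks of its genes in order being 0.434, and this test was set up once the median of the whole chromosome was known. A different number of copies of these chromosomes in clone 2 may be a candidate explanation, but no DNA measurement was used here and no biological explanation was tested. Shifts occurred in expressing lines too, the largest in clone 9 on chromosome 18 (0.354), and 14 of 20 chromosomes in clone 9 lay farther from 0 than any random list, against 16 in clone 2.

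For the 397 probe sets that followed Aqp2, 2 of 100 orders of the Aqp2 values, the real one included, gave as many, the highest other count being 532, but only 17 of the 100 kept clone 2 lowest and the others gave at most 29, so this count mostly restates the place of clone 2. With clone 2 kept lowest, 4 of 100 orders, the real one included, gave as many (median 1, highest other 532). Among all 120 such orders, from which those 100 were drawn, 4 did (3.3%), counted after the result was seen. This argues against the place of clone 2 alone setting the number of calls. It does not show that the calls hold apart from clone 2. Without clone 2 only 3 probe sets were called, and 1 of the 397 was still called. After each line's chromosome medians were removed, 167 of the 397 were still called. This argues against an equal shift of all genes of a chromosome as the whole cause. Genes that shift more than their chromosome's median, or shifts of part of a chromosome, would outlast the removal. Chromosome shifts as the whole cause thus stay open. They may be part of the cause, since the removal left 179 calls in all, against 358 to 395 when genes were assigned to chromosomes at random. All 397 kept their sign under it, and the 230 that lost their call went from a median absolute slope of 0.218 (median SE 0.041) to 0.183 (0.041), with a smaller slope in 198, while 84 lost it at an unadjusted p that had been low enough before. Of the 230 called genes with a chromosome, 31 lay on chromosome 17, all rising (Fisher's exact test, adjusted p = 5.74e-06). That test takes genes as independent, but genes of this chromosome shifted together, so its p overstates the evidence. A shared regulation with Aqp2 was not tested.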

How the results depend on the processing

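The removal of chromosome medians, and an estimated correlation with a line left out, were chosen after seeing the data, and all other settings were fixed before. Of 184 higher and 376 lower probe sets in clone 2, there were 76 and 134 with no filter, 69 and 150 without the mean-variance trend, 116 and 246 at a 2-fold minimum, 202 lower with 1 probe set per gene, 238 lower by a 2-fold difference outside the range of the other lines with no test, and 112 higher with chromosome medians removed. Leaving out each expressing line gave 45 to 325 higher and 109 to 618 lower, the extremes being without the original cells and without clone 9. Of 230 rising and 167 falling probe sets in the slope on Aqp2, there were 30 and 21 with no filter, 0 and 1 without the trend, 4 and 5 at a 2-fold minimum per doubling of Aqp2, 3 and 4 with Aqp2 on the linear scale, 91 and 88 with chromosome medians removed, 146 rising with quantile normalization and 139 rising with 1 probe set per gene. A rank correlation of exactly 1 was found for 147, and of -1 for 115, where chance gives 31.3 each if every order of the lines is equally likely. Genes that shift together can make some orders more frequent, and other orders were not counted, so the excess cannot be tied to Aqp2. Leaving out each line gave 0 to 392 rising and 0 to 256 falling. For the original cells, the 1 call became 0 with the filter at the 75th percentile or without probe sets that can match several transcripts, and 2 with the offset doubled, with a robust fit or against all 5 clones. A 2-fold minimum can only lower a count, and for the other settings the cause was not tested. Of the 35 called genes named for clone 2, 17 kept their call in every setting that gave a value, 18 lost it in at least 1, and none changed sign. Among the named list members, Ndrg1, Aqp6, Bst1, Hoxd8, Rxra and Gbp2 had other probe sets past the filter with the same sign, but none was called. Such a probe set was called for Npnt, Lrp2, Fn1, Nfat5, Rrm2, Slc2a1 and Rsad2. All 10 named slopes lost their call in at least 1 setting. Of the 7 lists past the threshold in clone 2 and 6 in the slope, all lost it with an estimated correlation and none with chromosome medians removed at the preset correlation. Leaving out each line gave an adjusted p from 0.00655 to 0.783 for the slope of the principal cell list, from 0.0151 to 0.982 for other kidney transcription factors and from 0.000812 to 0.753 for hypoxia and glycolysis. The highest of each was without clone 2, where the direction reversed, and the cause was not tested. With an estimated correlation, their adjusted p without clone 2 was 0.912, 0.98 and 0.912, again reversed, and no list passed in any comparison with any line left out. Another Aqp2 probe set could not be tried, since the array has 1. No paired analysis was possible because each line is a separate culture with no partner. Signals near the offset of 18.85 limit what the arrays resolve, so a fold against such a signal is not exact.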

Other observations

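The chromosome medians and the tests below were chosen after the data were seen, except that of shared direction within the expressing lines. Chromosome medians differed between expressing lines as well. Genes of chromosome 17 had a median log2 deviation from the other lines of 0.191 in clone 9 and 0.177 in clone 11, against -0.063 in clone 3 and -0.076 in clone 10. Genes of chromosome 9 had 0.227 and 0.172 in clones 9 and 11, against -0.198 and -0.184 in clones 3 and 10. Over the 6 lines, the chromosome 17 median followed Aqp2 with r = 0.981 (exact permutation p = 0.00278, adjusted 0.0278 over 20 chromosomes) and rho = 0.943 (p = 0.0167, adjusted 0.0668), and r was 0.885 without clone 2 and clone 11. For chromosomes 6, 7 and 13 r was -0.963, -0.953 and -0.912 (adjusted exact permutation p = 0.0278, 0.0347 and 0.0278), and -0.794, -0.810 and -0.797 without those lines.

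Whether fewer copies of the chromosome that carries Aqp2 went with its low signal in clone 2 was examined. Whether a change in copies could lower a signal that far was not tested. The median deviation of chromosome 15 genes in clone 2 was 0.136 (bootstrap SE 0.022), above the other lines, which argues against fewer copies of the whole chromosome. A median over 400 genes cannot show a loss confined to the region of Aqp2, which was not tested. Aqp6, also on chromosome 15, was lower in clone 2 as well, while Ndrg1 on the same chromosome was higher. Their positions relative to Aqp2 were not examined, so they do not show whether a local loss occurred.

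A further hypothesis was that genes that set clone 2 apart may also follow Aqp2 among the 5 expressing lines. Of the 559 calls other than Aqp2, 60.6% had a slope in that direction, where the highest of the 120 orders of the Aqp2 values gave 67.6% (one-sided exact permutation p = 0.175), so the share was not distinguishable from that of other orders. Of the 26 interferon response genes, 20 had a falling slope on Aqp2 within the expressing lines, a count of signs and not of calls. The slope of the list's mean was -0.259 (one-sided exact permutation p = 0.117).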
